A study of Homo sapiens with 12 samples.

How the data were processed

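Skin biopsies of 6 patients with prurigo nodularis, a chronic skin disease with intensely itchy nodules, were profiled by single-cell RNA sequencing. Each patient gave 1 biopsy of a nodule and 1 of skin without a nodule, so that 12 libraries form 2 groups of 6, lesional and nonlesional. Per the labels' protocols, epidermis and dermis were separated with dispase and digested apart, the epidermis with trypsin and the dermis with collagenases, and cells of both layers were then mixed in equal parts. Libraries were made with 10x Genomics version 3 chemistry and read on an Illumina NovaSeq instrument, per the labels' protocols. Reads were processed with Cell Ranger on the human genome build GRCh38 (also named as hg38), per the submitters' processing notes, and the Cell Ranger version, annotation release and cell-calling setting are not given in the sources used here. The deposited values are raw UMI counts (unique molecules per gene and cell barcode), with no normalization, in 1 sparse matrix per library with the same 33538 genes, each given by an Ensembl identifier and a symbol. The matrices hold 80 to 6840 barcodes each, of which 33 to 752 have fewer than 200 genes. Whether these are empty droplets was not tested, and free RNA was not measured directly.

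All values below were computed from those counts. XIST, TSIX and Y-linked genes, 102 in all, were removed first. Barcodes with fewer than 200 genes, fewer than 500 UMIs or more than 20% mitochondrial UMIs were left out, which kept 44700 of 50660 barcodes. Doublets were scored with Scrublet as run by scanpy in the 10 libraries with at least 200 kept cells. The automatic threshold marked 257 cells, 0.57% of those kept and few for libraries of this size, so the highest-scoring cells were removed at an expected rate of 0.8% per 1000 cells, 1681 cells in all, which left 43019. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes and 40 principal components fed a graph of 15 neighbors, and Leiden clustering at resolution 1 gave 30 clusters. No integration across libraries was applied. A cluster took the name of the cell class whose marker genes stood highest in it against the other clusters, as "fibroblast-like" and so on. Marker genes were chosen before the data were examined, and at least 3 of the class had to be detected. A cluster with few UMIs for its libraries was left unnamed if no marker of the class was among its top 10 genes. The 2 clusters left unnamed held 339 cells, 0.78% of lesional and 0.80% of nonlesional cells. One of them was led by the hemoglobin genes HBB and HBA2 and the other by IQCN, with the nuclear RNA NEAT1 among its 10 leading genes. The deposited data hold no cell annotation, so these classes are rebuilt names.

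Cells are not replicates, so raw counts were summed per library and class and tested across libraries. Libraries with at least 20 cells of a class entered, and a class was tested with at least 3 such libraries in each group. Sums were normalized by TMM, filtered with filterByExpr and tested with edgeR's quasi-likelihood test, lesional against nonlesional, without a block, two-sided, with Benjamini-Hochberg adjustment over the genes of the class and a threshold of 0.05. Fold changes are edgeR estimates, their standard errors (SE) are on the log2 scale, and levels are CPM, counts scaled to the same total in each library, as mean ± SD over libraries. "Rose" and "fell" are used of genes past that threshold and of lists past the list test. Fibroblast-, keratinocyte-, T or NK-, myeloid-, vascular endothelial- and mural-like cells were the 6 main classes, and 7 further classes were tested as secondary ones. Schwann-like and B or plasma-like cells reached too few libraries for a test.

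The genes named were chosen by rule: in fibroblast- and keratinocyte-like cells the 10 higher and 10 lower genes with the smallest p among those past the threshold with an absolute log2 fold change of at least 1, in the other main classes the 6 higher and 6 lower, or the 3 and 3 with the smallest p where none passed. The rule adds up to 4 members of each gene list called in a class, 8 receptor and ligand genes in each main class, and fixed structural and epidermal genes in fibroblast- and keratinocyte-like cells. Clone-named genes, immunoglobulin and T cell receptor segments and genes with common donor haplotypes are not named. The 19 gene lists, with at least 5 tested members, cover extracellular matrix, myofibroblast and contractile genes, TGF-beta response, inflammatory fibroblast genes and chemokines, receptors of the IL-31, OSM, IL-4 and IL-13 axis, cytokine ligands, T helper 2 and regulatory T cells, cytotoxic and type 1 lymphocytes, alternatively activated myeloid cells, JAK-STAT feedback, interferon response, keratinocyte activation and alarmins, cornified envelope, basement membrane and hemidesmosomes, proliferation, endothelial activation, neurotrophins with axon guidance and itch, immediate early and heat shock genes, and hypoxia with glycolysis. Lists were tested with camera at its preset correlation of 0.01, with adjustment over all 177 list and class pairs, and again with camera's estimated correlation, with fry, and with an exact permutation test of the list mean. The groups, tests, named-gene rule, markers, lists and most alternatives were fixed before the data were examined.

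Shares of classes were taken among cells other than keratinocyte-, adnexal epithelium-, melanocyte- and Langerhans-like cells. Both layers were mixed after digestion, so the epidermal share need not reflect the tissue. Shares were compared by a two-sided exact permutation test of the means over the 10 libraries with at least 200 cells. That test has 210 arrangements, a smallest p of 0.00476, and Benjamini-Hochberg adjustment over 9 classes.

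The titles give both libraries of a patient the same code, so the replicate numbers pair the groups. Same-patient libraries deviated together from their group means in fibroblast-like cells with a mean correlation across genes of 0.171 (smallest 0.0589) and in keratinocyte-like cells with 0.151 (smallest 0.068). In T or NK-like cells the mean was 0.0281 with a smallest value of −0.0875. It was 0.125 (smallest −0.0885) in myeloid-like, 0.183 (0.101) in vascular endothelial-like, 0.199 (0.125) in mural-like, 0.269 (0.154) in basal and 0.251 (0.124) in suprabasal keratinocyte-like cells. The fit with the patient as a block was run as an alternative, and its value stands beside a printed test where it ends or adds a call or moves a count by over 1.5 times.

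The edgeR step was tested on simulated data drawn from the real means and library sizes, with 200 genes changed. Among genes changed 4-fold it recovered 87.9% in fibroblast-like, 74.2% in keratinocyte-like, 83.3% in T or NK-like, 53% in myeloid-like, 77.3% in vascular endothelial-like and 77.3% in mural-like cells. Among genes changed 2-fold it recovered 20.9%, 22.4%, 28.4%, 3%, 23.9% and 17.9% in the same order, and 1.5-fold changes were recovered in at most 4.5%. Unchanged genes made up at most 6.9% of calls, and none was called when no gene changed. These simulated data held no patient effect. The block was run on other simulated data with a patient effect added for each gene, where the fit without it was not run. There unchanged genes made up 23.5% of calls in fibroblast-like and 14.8% in keratinocyte-like cells. The shares therefore do not compare the fits with and without the block.

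Depth differed by library. Total UMIs ranged from 35390878 to 79447163 in lesional libraries. Nonlesional replicates 3 to 6 held 39039065 to 72829869, but nonlesional replicates 1 and 2 held 56541 and 147868 UMIs in 80 and 179 barcodes. After filtering these had 34 and 27 cells, and they enter only the fibroblast test (nonlesional replicate 1, 31 cells) and the keratinocyte test (nonlesional replicate 2, 21 cells). Where a group holds 0 counts, a floor of 3 counts over the group gives a lower bound, and ratios with 1 to 3 counts in a group carry a 95% interval for counting error only.

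Alternatives covered another normalization (RLE), DESeq2, no low-count filter, the block, only patients with both libraries, at least 50 or 10 cells per library, doublets kept or removed by the automatic threshold, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), classes from marker scores, each library left out, other denominators for shares and other list tests. Trajectories, cell-to-cell signalling scores and sub-clusters were not analysed here. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.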

Results

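The study asked how immune and stromal cells differ between nodules and other skin in prurigo nodularis. The 12 libraries, 6 lesional and 6 nonlesional from the same 6 patients, gave 43019 cells after filtering. Total UMI counts of lesional replicates 1 to 6 were 60331679, 35390878, 48511155, 36351989, 79447163 and 61445723. Those of nonlesional replicates 1 to 6 were 56541, 147868, 42340142, 39039065, 72829869 and 52786612. Nonlesional replicates 1 and 2 kept only 34 and 27 cells, so comparisons rest on 3 to 6 lesional and 3 to 5 nonlesional libraries. Keratinocyte-like cells made up 1.86% to 81% of the cells of a lesional library and 46.5% to 87.8% of those of a nonlesional library with at least 200 cells.

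Fibroblast-like cells, the matrix-making cells of the dermis, carried a strong matrix program in nodules. Extracellular matrix genes rose as a list (48 tested members, median log2 fold change 1.21; adjusted p = 0.1025 with an estimated correlation), with 17 members higher, 0 lower and 31 not past the test. COL1A1 and COL1A2, the chains of type I collagen, rose 6.42-fold (log2 2.68, SE 0.55) and 4.26-fold (log2 2.09, SE 0.49), from 5416 ± 3756 to 34920 ± 16000 CPM for COL1A1 (SD, n = 5 nonlesional and 6 lesional libraries). COL3A1, of type III collagen, rose 4.64-fold (SE 0.59) and the matrix glycoprotein TNC 6.22-fold (SE 0.57). TNC stood at 2190 CPM in lesional replicate 1 against a mean of 449 CPM in the other lesional libraries. COL10A1, a collagen best known from growth-plate cartilage, rose 47.7-fold (log2 5.58, SE 0.88), and CTHRC1, a secreted protein of collagen-producing fibroblasts, 5.72-fold (log2 2.52, SE 0.40).

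Other genes with the smallest p also set lesional fibroblast-like cells apart. Higher were GLIS3, a zinc finger transcription factor (8.62-fold, SE 0.37), the kinase gene ALPK2 (11-fold, SE 0.44), ADAMTS2, which trims procollagen (3.86-fold, SE 0.27), SPHK1, which makes sphingosine 1-phosphate (34.3-fold, SE 0.72), and ANGPTL2 (3.62-fold, SE 0.27). HAPLN3, EEF1AKMT4, NREP, CD68 and SAT1 rose between 2.98- and 7.83-fold. Lower were the leptin receptor LEPR (14.3-fold, SE 0.58, from 513 ± 184 to 36.7 ± 29.5 CPM), the ciliary neurotrophic factor receptor CNTFR (8.54-fold, SE 0.44), the GDNF co-receptor GFRA1 (3.68-fold, SE 0.21) and the axon guidance ligand SLIT2 (2.66-fold, SE 0.21). TMEM132C, AKAP6, PTPN13, PPP1R12B, NFIA and SLC25A21-AS1 fell between 2.57- and 17.6-fold. The adjusted p of these 20 genes was 0.0023 to 0.00455 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

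Part of the genes of activated fibroblasts and of TGF-beta signalling rose as well. Of 16 members of the myofibroblast and contractile list 4 rose and 0 fell (median log2 0.75, adjusted p = 0.1234 with an estimated correlation), led by the protease gene ADAM12 (27.5-fold, SE 0.73), the activated fibroblast markers LRRC15 (3.13-fold, SE 0.29) and FAP (2.95-fold, SE 0.32), and the signalling ligand WNT5A (9.57-fold, SE 0.72, edgeR adjusted p = 0.0222). Of 20 TGF-beta response genes 4 rose and 0 fell (median log2 0.60, adjusted p = 0.2058 with an estimated correlation), among them TGFB3 (3.06-fold, SE 0.26), LTBP2 (5.31-fold, SE 0.42), PMEPA1 (3.44-fold, SE 0.36) and LTBP1 (2.68-fold, SE 0.35). Not past the test were POSTN (3.39-fold, SE 0.50, edgeR adjusted p = 0.0546, and 0.015 with the block), COL11A1 (2.92-fold, SE 1.00, 0.381), the smooth muscle actin gene ACTA2 (log2 −0.04, SE 0.39, 0.976, and log2 0.77 without nonlesional replicate 3) and CTGF (log2 0.35, SE 0.37, 0.63). The contractile genes MYL9, TAGLN, TPM1 and TPM2 did not pass either (edgeR adjusted p = 0.0679, 0.212, 0.393 and 0.915), and with the block the first 2 did (0.0322 and 0.045). Among 20 cell cycle genes TOP2A (24.1-fold, SE 0.98) and CENPF (4.65-fold, SE 0.53) rose and 18 did not pass (median log2 1.87, adjusted p = 0.7747 with an estimated correlation for the list). In the neurotrophin and axon guidance list SLIT2, SEMA3A (2.46-fold) and SEMA3D (2.81-fold) fell, NRP2 rose (4.25-fold, SE 0.52) and 12 members did not pass (adjusted p = 0.3387 with an estimated correlation). Its median log2 fold change was −0.36 while the difference of list means was 0.065 (exact permutation p = 0.948), so median and mean differ in sign.

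Adjusted over the list alone, 33 matrix, 7 myofibroblast, 5 TGF-beta, 10 proliferation, 1 higher and 3 lower neurotrophin genes passed in fibroblast-like cells. The camera adjusted p was 3.415e-20, 2.75e-05, 0.000129, 0.004525 and 0.01782 for these 5 lists, and with an estimated correlation the adjusted p was 0.1025, 0.1234, 0.2058, 0.7747 and 0.3387. In each of the first 3 lists all 6 lesional libraries lay above the highest nonlesional one (exact permutation p = 0.00216, 0.00216 and 0.00433). A sixth list, keratinocyte activation, rose as well (median log2 3.31, 5 members higher, 6 not past the test, 9 adjusted over the list alone, adjusted p = 0.4192 with an estimated correlation). Its members KRT6A (32.8-fold, SE 1.05, to 23.6 ± 17.8 CPM), SPRR1B and KRT6C are epidermal genes, which stood at 6188 ± 4694 CPM for KRT6A in lesional keratinocyte-like cells. KRT6C had 716 counts against 1, a ratio of 110 with an interval of 19.6 to 4340. FABP5, a fatty acid carrier, rose 3.22-fold (SE 0.39). Markers of myeloid cells, which include CD68, stood at 104 ± 26.1 CPM in lesional and 46.6 ± 7.7 CPM in nonlesional fibroblast-like cells (exact permutation p = 0.00216).

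In all, 661 of 12679 genes passed in fibroblast-like cells, 396 higher and 265 lower (6 lesional against 5 nonlesional libraries). With the patient as a block 1253 passed, along with the inflammatory and chemokine list (19 members, median log2 0.21, camera adjusted p = 0.0004743 with the block and 0.4386 without) and the interferon list (0.0116 and 0.1625). Different clusters held the class in each group: cluster 4, led by collagen genes, had 43.1% of lesional and 0.78% of nonlesional fibroblast-like cells, cluster 5, led by LEPR, 10.1% and 50.6%, cluster 8, led by C3, 24.5% and 48.7%, and cluster 2, which came to 92.6% from lesional replicate 1, 22.4% of the lesional ones. Leaving out nonlesional replicate 3, 4 or 5 lowered the count to 213, 109 or 248, and leaving out lesional replicate 3 or 5 to 406 or 385. Of 45 named genes past the test, 26 kept their call without each library for which they were tested, while COL3A1 and SEMA3D lost it without 8 of 11 libraries (highest edgeR adjusted p = 0.131 and 0.147), LTBP1 without 6 (0.118), COL1A2, TNC and WNT5A without 3 and COL1A1 without 1.

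**Figure D1:**
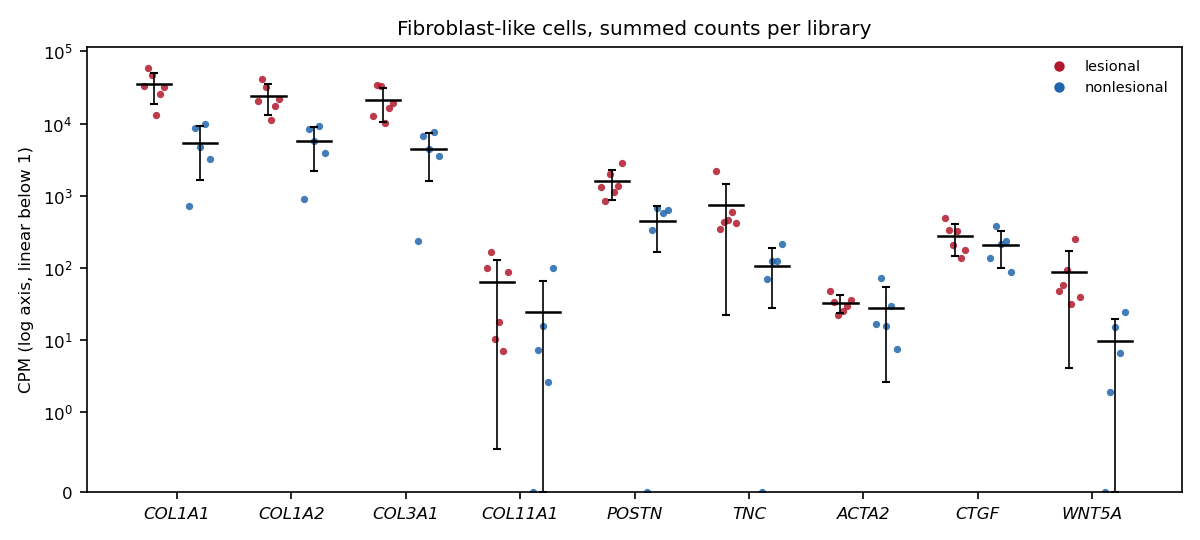
CPM of 9 structural and signalling genes in fibroblast-like cells on a log axis that is linear below 1, with 1 point per library (6 lesional, 5 nonlesional), a horizontal line at the mean and bars of 1 SD that stop at 0. COL1A1 has a lesional mean of 34920 and a nonlesional mean of 5416 CPM, while ACTA2 has means of 32.5 and 28.1 CPM.

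Interferon genes and part of the activation genes rose in keratinocyte-like cells of nodules. Neither list call held with an estimated correlation. Interferon response genes rose as a list (median log2 2.68, adjusted p = 0.2058 with an estimated correlation), with 17 of 21 members higher, 0 lower and 4 not past the test. IFITM3, which blocks viral entry, rose 6.02-fold (log2 2.59, SE 0.35, from 51.9 ± 29.2 to 344 ± 108 CPM, n = 5 and 6), and the antiviral oligoadenylate synthetase genes OAS2, OAS3 and OASL rose 14.4-fold (SE 0.61), 4.58-fold (SE 0.32) and 19.4-fold (SE 0.70). The wound keratins KRT6A, KRT16 and KRT17 rose 30.8-fold (SE 1.35), 26.6-fold (SE 1.01) and 15.4-fold (SE 1.04), KRT16 from 380 ± 540 to 10350 ± 6852 CPM. S100A2 rose 7.2-fold (SE 0.58), FABP5 7.94-fold (SE 0.70) and the protease inhibitor SERPINB4 22-fold (SE 1.39, edgeR adjusted p = 0.0486). The alarmins S100A8 (35-fold, SE 1.69) and S100A9 (28.6-fold, SE 1.72) varied more between libraries and missed the threshold (edgeR adjusted p = 0.0576 and 0.074, and with the block 0.000646 and 0.000201).

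Terminal differentiation genes did not move as a group. Of 28 cornified envelope members 0 passed in either direction (median log2 0.38, camera adjusted p = 0.8861), with KRT1 at log2 −0.07 (SE 0.30), KRT10 at 0.10 (SE 0.32), FLG at 0.51 (SE 0.93) and LOR at 0.19 (SE 1.13). Without lesional replicate 1, which has 82 of these cells, FLG stood at log2 −0.56 and LOR at −1.50 (edgeR adjusted p = 0.633 and 0.266), and KRT1 and KRT10 turned direction without 2 libraries each, at an absolute log2 of 0.20 or less. Adjusted over the list alone, again 0 passed. Cell cycle genes rose as a list (9 of 22 higher, 0 lower, median log2 1.25, adjusted p = 0.637 with an estimated correlation), with MKI67 at 3.08-fold (SE 0.35), BIRC5 at 3.55-fold (SE 0.43), TPX2 at 2.71-fold (SE 0.25) and AURKA at 2.91-fold (SE 0.32). Cluster 21, with TOP2A and MKI67 among its leading genes, held 8.24% of lesional and 2.11% of nonlesional keratinocyte-like cells. The rise therefore need not be a change within each cell. That cluster is in neither the basal nor the suprabasal class. Of 18 hypoxia and glycolysis genes 5 rose, among them the enzymes ENO1 (2.97-fold, SE 0.28), PKM (2.29-fold, SE 0.27), ALDOA (1.67-fold, SE 0.16) and HK2 (3.14-fold, SE 0.43). That list's camera adjusted p was 0.03982, against 0.4487 with the block and 0.7747 with an estimated correlation.

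The strongest single genes included higher TYMP, thymidine phosphorylase (6.44-fold, SE 0.27), PITX1, a homeobox transcription factor (19.4-fold, SE 0.54), CAPN2 (4.42-fold, SE 0.26) and the noncoding RNA PVT1 (4.12-fold, SE 0.25). SIPA1L2, ADAMTS7, POLR3G, GATB and RFTN1 rose between 3.03- and 9.57-fold. Lower were FHL1 (8.49-fold, SE 0.28, from 31.5 ± 2.7 to 3.78 ± 1.72 CPM), the suprabasal keratin KRT77 (19.9-fold, SE 0.57), the desaturase gene SCD5 (7.75-fold, SE 0.31) and the cation channel gene TRPC6 (12.8-fold, SE 0.50). CMYA5, CLDND1, ADD3, PELI2, GATM and MCF2L fell between 2.65- and 6.27-fold. The edgeR quasi-likelihood adjusted p of these 19 genes and of IFITM3 was 0.000706 to 0.00286 with Benjamini-Hochberg adjustment.

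Matrix genes also passed in keratinocyte-like cells, with 10 of 39 higher, 2 lower and a median log2 of 1.74 (adjusted p = 0.7808 with an estimated correlation). COL1A1 (77.5-fold, SE 1.46), COL3A1 (81.1-fold, SE 1.44) and TNC (26-fold, SE 1.08) rose and P4HA1, a collagen hydroxylase subunit, fell 2.68-fold (SE 0.31). COL1A1 stood at 1764 CPM in lesional replicate 1, which has 82 keratinocyte-like cells, and at 9.59 to 75.2 CPM in the other lesional libraries. Without that library COL1A1 was 11.3-fold, COL3A1 15.7-fold and TNC 9.84-fold higher (edgeR adjusted p = 0.00273, 0.00353 and 0.00602). Markers of fibroblasts in this class were 818 ± 1406 CPM in lesional and 122 ± 40.2 CPM in nonlesional libraries (exact permutation p = 0.039), and markers of basal keratinocytes 39660 ± 16360 and 18700 ± 2123 CPM (exact permutation p = 0.00649).

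Adjusted over the list alone, 18 interferon, 22 activation, 14 proliferation, 8 higher and 2 lower hypoxia, and 19 higher and 2 lower matrix genes passed. Of the 29 activation genes 14 passed over all genes tested (median log2 3.94). The camera adjusted p was 2.962e-14 for interferon, 8.433e-09 for activation, 5.967e-06 for proliferation and 0.00693 for matrix genes, and with an estimated correlation the adjusted p was 0.2058, 0.4969, 0.637, 0.7808 and, for hypoxia, 0.7747. All 6 lesional libraries lay above the highest nonlesional one in the interferon list (exact permutation p = 0.00216) and 5 of 6 in the activation list (0.0108).

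In all, 1987 of 13856 genes passed, 1072 higher and 915 lower (6 lesional against 5 nonlesional libraries), and 3876 with the block. Lesional cells lay mostly in clusters 10 (26.6%), 27 (18.9%) and 15 (15.9%), and nonlesional ones in clusters 22 (35.2%), 23 (22.6%) and 28 (18.3%). Leaving out nonlesional replicate 3, 4, 5 or 6 gave 591, 639, 1184 or 1042 calls and leaving out lesional replicate 3 or 5 gave 1059 or 983. Of 43 named genes past the test 30 kept their call without each library for which they were tested, while SERPINB4 lost it without 8 of 11 (highest edgeR adjusted p = 0.101), KRT6A without 6, HK2 without 5, KRT17 without 4 and FABP5 without 2.

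**Figure D2:**
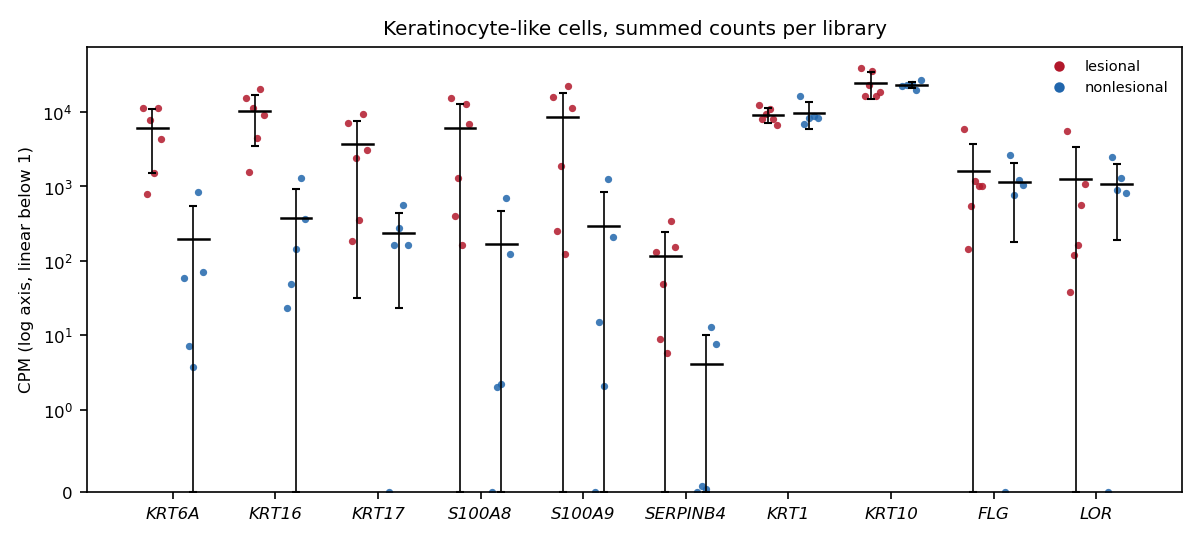
CPM of 10 epidermal genes in keratinocyte-like cells on a log axis that is linear below 1, with 1 point per library (6 lesional, 5 nonlesional), a horizontal line at the mean and bars of 1 SD that stop at 0. KRT16 has a lesional mean of 10350 and a nonlesional mean of 380 CPM, while KRT10 has means of 24860 and 23210 CPM.

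T or NK-like cells of nodules had few genes past the test. IL2, a T cell growth factor, fell 4.95-fold (log2 −2.31, SE 0.37, from 87.9 ± 48.8 to 19.9 ± 14.3 CPM, n = 4 nonlesional and 6 lesional libraries) and CSF2, which encodes the cytokine GM-CSF, 6.24-fold (SE 0.42). The lysosomal enzyme gene GLA fell 4.22-fold (SE 0.29), the amino acid transporter gene SLC38A2 2.29-fold (SE 0.19), HSPA2 3.66-fold (SE 0.30) and RCBTB2 2.54-fold (SE 0.23). CD7, a surface protein of T and NK cells, rose 2.27-fold (SE 0.23, edgeR adjusted p = 0.0434).

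Single members of the lists did not pass over all genes in T or NK-like cells, but 5 lists did, none of them with an estimated correlation (adjusted p = 0.1025 to 0.416). Interferon genes rose (12 members, median log2 1.15, 7 adjusted over the list alone), with MX1 at 3.42-fold (SE 0.53) and IFI6 at 2.79-fold (SE 0.47). T helper 2 and regulatory T cell genes rose (13 members, median log2 0.40, 3 higher and 1 lower adjusted over the list alone). Their members parted: the regulatory T cell genes CTLA4 and FOXP3 stood at 2.62-fold (SE 0.40) and 2.59-fold (SE 0.50) and the activation factor BATF at 1.82-fold (SE 0.28) higher, while the type 2 cytokine IL13 stood 3.47-fold lower (SE 0.64), with its nonlesional counts in 2 of 4 libraries and its lesional ones in all 6. TGF-beta response genes fell (8 members, median log2 −0.56, 3 adjusted over the list alone), with ID3 2.42-fold (SE 0.30) and TGFB1 1.56-fold (SE 0.24) lower. Immediate early and heat shock genes, which tissue dissociation also induces, fell (22 members, median log2 −0.55, 1 adjusted over the list alone), with EGR2 2.73-fold (SE 0.35) and NR4A1 1.80-fold (SE 0.28) lower. Keratinocyte activation genes rose (5 members, median log2 2.80, 4 adjusted over the list alone), with KRT16 at 82.9 ± 65.8 against 9.71 ± 19.4 CPM and S100A2 at 129 ± 217 against 12 ± 4.46 CPM, which passed with the block alone (edgeR adjusted p = 0.0436 and 0.025). Among other lists of this class, cytotoxic genes were not called (14 members, median log2 0.19, camera adjusted p = 0.3376).

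The camera adjusted p was 1.812e-06, 0.01006, 0.005291, 5.66e-09 and 3.979e-06 for these 5 lists in the order given, and with an estimated correlation the adjusted p was 0.1314, 0.416, 0.2559, 0.152 and 0.1025. The exact permutation p was 0.00476 for the interferon, TGF-beta and activation lists, 0.0143 for the immediate early list and 0.0333 for the T helper list. In all, 16 of 4540 genes passed, 2 higher and 14 lower, and 26 with the block. Under it 2 of the 8 genes chosen by rule lost their call, among them RCBTB2 (edgeR adjusted p = 0.0957). All genes named above as past the test lost their call without nonlesional replicate 5, which left 0 calls, and the count was 10 without lesional replicate 3, 8 without lesional replicate 2, nonlesional replicate 3 or nonlesional replicate 4 and 6 without nonlesional replicate 6.

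Myeloid-like cells, macrophages and dendritic cells, had no gene past the edgeR test, with 0 of 5269 genes called, 582 at an unadjusted p under 0.05, 34 by DESeq2 and 2 with the block. The smallest p belonged to higher IFI27, an interferon-induced gene (31.9-fold, SE 0.94), UBE2L6 (4.57-fold, SE 0.48) and ABI3 (5.7-fold, SE 0.56) and to lower GPATCH2 (3.51-fold, SE 0.32), TTC14 (3.82-fold, SE 0.35) and SNHG12 (2.78-fold, SE 0.30), all at an edgeR adjusted p of 0.167. 6 lists were called, none of them with an estimated correlation (adjusted p = 0.1025 to 0.6952). Interferon genes rose as a list (13 members, median log2 0.83, camera adjusted p = 0.0005397), with GBP1 at 2.52-fold (SE 0.60) and all 6 lesional libraries above the nonlesional ones (exact permutation p = 0.00476). Inflammatory and chemokine genes rose (11 members, median log2 1.05, camera adjusted p = 0.01237), with the monocyte attractant CCL2 at 7.98-fold (SE 0.83) and CXCL1 at 4.6-fold (SE 0.89). Hypoxia and glycolysis genes rose (11 members, median log2 0.37, camera adjusted p = 0.02357), with ADM at 3.47-fold (SE 0.65). Keratinocyte activation genes rose (8 members, median log2 2.35, camera adjusted p = 0.000789), with S100A8 at 161 ± 189 against 11.3 ± 14.5 CPM and KRT16 at 359 counts against 2, a ratio of 21.7 with an interval of 5.97 to 180 (KRT16 passed with the block, edgeR adjusted p = 0.0448). Cornified envelope genes, which are epidermal, fell (9 members, median log2 −1.13, camera adjusted p = 0.004194), with DMKN at 557 ± 594 against 1534 ± 1377 CPM. DMKN stood at 3590 CPM in nonlesional replicate 4, which has 22 myeloid-like cells. Suprabasal keratinocyte markers stood at 4270 ± 5068 against 9810 ± 7787 CPM in this class (exact permutation p = 0.124). Whether keratinocyte RNA gives the fall was not tested.

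Matrix genes rose as a list in myeloid-like cells (10 members, median log2 3.66, camera adjusted p = 0.00693, and 0.07114 with the block), with COL1A1 at 7260 CPM in lesional replicate 2 and a lesional mean of 1280 ± 2931 CPM. Fibroblast markers stood there at 3033 ± 6029 against 247 ± 71.1 CPM (exact permutation p = 0.333). With an estimated correlation the adjusted p of these 6 lists was 0.1025 for interferon, 0.4282 for chemokine, 0.4883 for hypoxia, 0.3387 for activation, 0.6952 for cornified envelope and 0.539 for matrix genes. Adjusted over the list alone, 2 interferon, 1 chemokine, 2 activation and 4 matrix genes passed, and 0 hypoxia and 0 cornified envelope genes. The list of alternatively activated myeloid genes was not called (17 members, median log2 0.33, camera adjusted p = 0.1937). Leaving out nonlesional replicate 6 gave 5 calls.

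Vascular endothelial-like cells, which line blood vessels, showed activation in nodules. Endothelial activation genes rose as a list (23 members, median log2 0.78, adjusted p = 0.2058 with an estimated correlation), with 4 higher, 0 lower and 19 not past the test. SELE, the adhesion molecule E-selectin, rose 2.68-fold (SE 0.27, from 907 ± 324 to 2434 ± 698 CPM, n = 4 and 6), COL4A1, a basement membrane collagen, 5.84-fold (SE 0.50), the insulin receptor INSR 2.25-fold (SE 0.21) and VWA1 2.52-fold (SE 0.27). CD200, a ligand of an inhibitory receptor on myeloid cells, rose 7.4-fold (SE 0.32), SMAD6, an inhibitor of BMP signalling, 4.53-fold (SE 0.32) and the matrix protease MMP2 4.67-fold (SE 0.33), and FSCN1, HMGB3 and ZFHX3 rose between 2.83- and 4.37-fold. Lower were the lipoprotein receptor SCARB1 (4.78-fold, SE 0.27), the glycerol channel AQP7 (4.98-fold, SE 0.40), OTULINL, PITPNM3, PPL and LINC02185 (3.53- to 5.81-fold). Their edgeR adjusted p was 0.00247 to 0.0176 for these 12 genes and 0.0231 to 0.0319 for the 4 list members.

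Of 29 matrix genes COL4A1 alone passed (median log2 1.44, adjusted p = 0.4835 with an estimated correlation), and it lost its call without 5 of 10 libraries (highest edgeR adjusted p = 0.127). COL4A1 stood at 2250 CPM in lesional replicate 1 against a mean of 529 CPM in the other lesional libraries. Fibroblast markers stood at 572 ± 825 CPM in lesional and 114 ± 136 CPM in nonlesional libraries of this class (exact permutation p = 0.276). Whether fibroblast RNA gives the rise of the matrix list here was not tested. Of 16 TGF-beta response genes TGFB1 alone passed, which encodes the ligand (2.17-fold, SE 0.23, edgeR adjusted p = 0.0319, median log2 of the list 0.63, and 0.4192 for the list with an estimated correlation). CTGF stood 2.62-fold lower (SE 0.38) and passed with the block alone (edgeR adjusted p = 0.0177). Cell cycle genes rose as a list (16 members, median log2 1.87, also with the 4 members without nonlesional counts at their bound, adjusted p = 0.4871 with an estimated correlation), with TOP2A at 227 counts against 3 (ratio 29.6, interval 9.99 to 144) and TPX2 at 122 against 0, at least 15.9-fold higher at a floor of 3 counts over the group, with a lower 95% limit of 12.7-fold. These genes passed with the block alone (edgeR adjusted p = 0.00375 and 0.00901). Immediate early and heat shock genes rose as a list (22 members, median log2 0.57), but not with an estimated correlation (adjusted p = 0.637), and 4 of 6 lesional libraries lay above and 1 below the nonlesional ones (exact permutation p = 0.195), with FOSB at 1.89-fold (SE 0.27) and BAG3 at 2.56-fold (SE 0.45, edgeR adjusted p = 0.00537 with the block). Keratinocyte activation genes rose (8 members, median log2 2.53, adjusted p = 0.5308 with an estimated correlation), with KRT6B at 162 counts against 2 (ratio 31.7, interval 8.62 to 264) and S100A9 at 37.5 ± 48.4 against 1.85 ± 3.33 CPM, which passed with the block alone (edgeR adjusted p = 0.00142 and 0.00114). Myeloid markers stood at 69.2 ± 22.3 against 34.4 ± 11.9 CPM in this class (exact permutation p = 0.019).

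The camera adjusted p of the endothelial, matrix, TGF-beta, proliferation, immediate early and activation lists was 1.155e-06, 3.792e-08, 0.02771, 5.534e-07, 0.0008424 and 0.0009079. With an estimated correlation the adjusted p was 0.2058, 0.4835, 0.4192, 0.4871, 0.637 and 0.5308. Adjusted over the list alone, 10 higher and 3 lower, 14 higher, 6 higher and 1 lower, 9 higher, 0 and 4 higher genes passed in the same order. The interferon list was called with the block alone (adjusted p = 0.02649, median log2 0.03 without it). In all, 95 of 10257 genes passed, 56 higher and 39 lower, and 598 with the block. Leaving out nonlesional replicate 3, 4, 5 or 6 gave 5, 28, 48 or 31 calls, leaving out lesional replicate 5 gave 38 and leaving out lesional replicate 2 or 4 gave 285 or 180, and 4 of 17 named genes (CD200, MMP2, SCARB1 and OTULINL) kept their call without each library.

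Mural-like cells, pericytes and smooth muscle, had 5 genes past the test (6 lesional against 3 nonlesional libraries). PI15, a secreted protease inhibitor family member, rose 12-fold (log2 3.59, SE 0.37, from 12.3 ± 7.33 to 151 ± 40.3 CPM, edgeR adjusted p = 0.00252). CPXM1, of the carboxypeptidase family, had 815 counts against 1, a ratio of 199 with an interval of 35.5 to 7850. HOXC10, a positional homeobox gene, fell 9.77-fold (SE 0.45), GFRA1 4.83-fold (SE 0.33) and STXBP6 4.75-fold (SE 0.34). PI15 alone kept its call without each library, while CPXM1 lost it without 5 of 9 libraries and the other 3 without 4 each (highest edgeR adjusted p = 0.272 to 0.276).

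Matrix genes rose as a list in mural-like cells (41 members, median log2 1.38, camera adjusted p = 3.415e-20, and 0.2466 with an estimated correlation) with all 6 lesional libraries above the nonlesional ones, although 0 members passed over all genes and 27 did adjusted over the list alone. VCAN stood at 13.7-fold (SE 0.66), POSTN at 7.11-fold (SE 0.50) and COL1A1 at 12.5-fold (SE 0.77), all past the test with the block (edgeR adjusted p = 0.000834, 0.000834 and 0.00125), and fibroblast markers in this class at 14760 ± 11680 against 2559 ± 394 CPM (exact permutation p = 0.0238). Interferon genes rose (19 members, median log2 0.93, camera adjusted p = 2.619e-07, and 0.2842 with an estimated correlation, 5 adjusted over the list alone), with IFI27 at 5.07-fold (SE 0.43) and IFIT3 at 3.97-fold (SE 0.39), which passed with the block (edgeR adjusted p = 0.000373 and 0.00161). Endothelial activation genes, of which SPARC, COL4A1 and COL4A2 are also matrix genes, rose (15 members, median log2 0.92, camera adjusted p = 0.0022, and 0.2058 with an estimated correlation, 5 adjusted over the list alone), and proliferation genes rose (13 members, median log2 0.67, camera adjusted p = 0.02233, and 0.7228 with an estimated correlation, 0 adjusted over the list alone). With the block the activation list rose (adjusted p = 1.277e-06), the cornified envelope list fell (6.677e-10), and 401 genes passed. DESeq2 called 161 genes. Leaving out nonlesional replicate 3, 4 or 5 gave 1, 2 or 2 calls, lesional replicate 3 or 5 gave 2 or 1, and lesional replicates 1, 2, 4 and 6 gave 26, 37, 77 and 23.

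Receptors and ligands of the type 2 and oncostatin M axes were followed in each main class whatever their result. IL31, the itch cytokine, had 0 counts in all 6 classes, which in T or NK-like cells allows up to 0.443 CPM in lesional and 1.92 CPM in nonlesional libraries. Its receptor gene IL31RA was detected mainly in fibroblast-like cells (56 and 5 counts, 0.799 and 0.465 CPM) and keratinocyte-like cells (78 and 35 counts, 0.454 and 0.217 CPM), and 60.3% of the lesional keratinocyte counts came from 1 library. OSM, the ligand oncostatin M, had 204 counts in lesional and 12 in nonlesional myeloid-like cells (28.1 and 13.6 CPM over the group, below the filter for the test), and 57.4% of the lesional ones came from 1 library. In T or NK-like cells it had 79 and 28 counts (11.7 and 18 CPM). Its receptor OSMR did not pass the test in fibroblast-like (log2 −0.10, SE 0.36, edgeR adjusted p = 0.926), keratinocyte-like (0.53, SE 0.43, 0.427), vascular endothelial-like (−0.36, SE 0.27, 0.565) and mural-like cells (0.57, SE 0.43, 0.574). OSMR in fibroblast-like cells turned to log2 0.05 without lesional replicate 2 and to 0.12 without nonlesional replicate 5. IL4R rose in keratinocyte-like cells (3.67-fold, SE 0.48, edgeR adjusted p = 0.0233) and was not past the test in the other 5 classes, where the log2 fold change ranged from 0.03 to 1.17. The lowest, in mural-like cells, turned to −0.16 without nonlesional replicate 4. IL4R lost its call in keratinocyte-like cells without lesional replicate 5 or nonlesional replicate 3, 4 or 6 (highest edgeR adjusted p = 0.0733). IL13RA1 stood at 2.95-fold (SE 0.50) in keratinocyte-like cells with an edgeR adjusted p of 0.0531, and 0.00957 with the block. TGFB1 rose in keratinocyte-like cells as well (2.29-fold, SE 0.30, edgeR adjusted p = 0.0222) and lost its call without nonlesional replicate 3, 4 or 6 (highest 0.0738). As lists, neither these receptors nor the cytokine ligands were called in a main class. In keratinocyte-like cells the receptors had a median log2 of −0.07 (19 members, camera adjusted p = 0.5785) against a difference of list means of 0.152, so median and mean differ in sign. The ligands had a median log2 of −0.63 in T or NK-like cells (7 members, camera adjusted p = 0.07212). JAK-STAT feedback genes (14 members, median log2 −0.19, 3 higher, 2 lower, camera adjusted p = 0.6409) and basement membrane genes (18 members, median log2 0.17, 2 higher, camera adjusted p = 0.5682) were not called in keratinocyte-like cells or another main class.

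**Figure D3:**
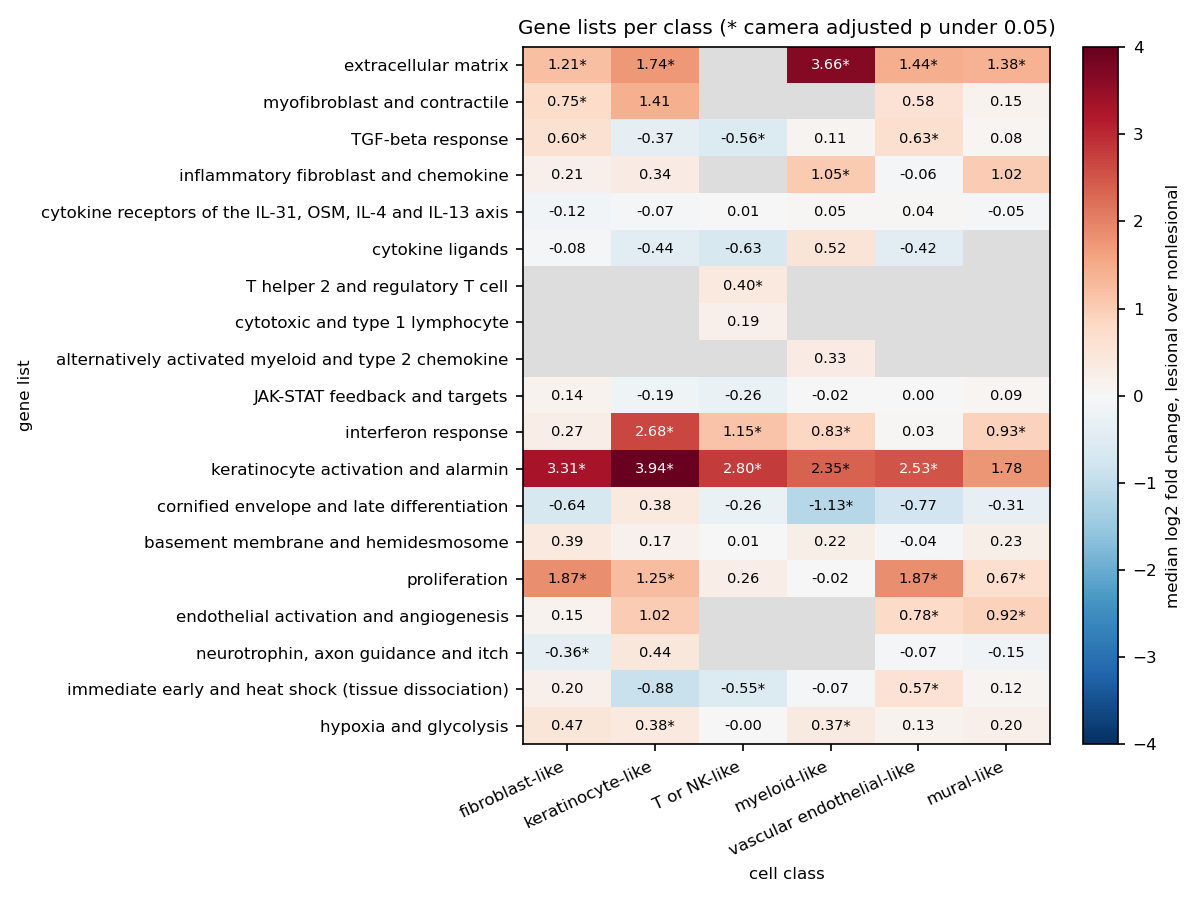
Median log2 fold change (lesional over nonlesional) of each gene list in each main class, with an asterisk where the camera adjusted p is under 0.05 and grey where fewer than 5 members were tested. The interferon list reads 2.68 in keratinocyte-like and 0.03 in vascular endothelial-like cells, and each asterisk is lost with an estimated correlation.

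Shares of cell classes did not differ detectably between groups. Fibroblast-like cells made up 42.4% ± 9.51 (SD, n = 6) of nonepidermal cells in lesional and 38.5% ± 3.95 (n = 4) in nonlesional libraries, T or NK-like cells 14.3% ± 8.92 and 10.7% ± 3.91, and myeloid-like cells 7.13% ± 3.12 and 5.1% ± 2.27. Vascular endothelial-like cells made up 14.6% ± 5.81 and 16.4% ± 6.38, mural-like cells 9.39% ± 2.36 and 12.9% ± 6.06, lymphatic endothelial-like cells 3.52% ± 2.01 and 5.76% ± 3.65, and mast-like cells 3.9% ± 2.04 and 4.17% ± 2.14. B or plasma-like cells made up 2.3% ± 3.95 and 0.106% ± 0.213, and Schwann-like cells 0.321% ± 0.297 and 0.452% ± 0.434. Adjusted p values over the 9 classes were 0.7286 to 0.8381 by the two-sided exact permutation test. The range within a group, such as 3.34% to 26.7% for lesional T or NK-like cells, was wider than these differences, and 4 patients with both libraries allow no paired p below 0.125.

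**Figure D4:**
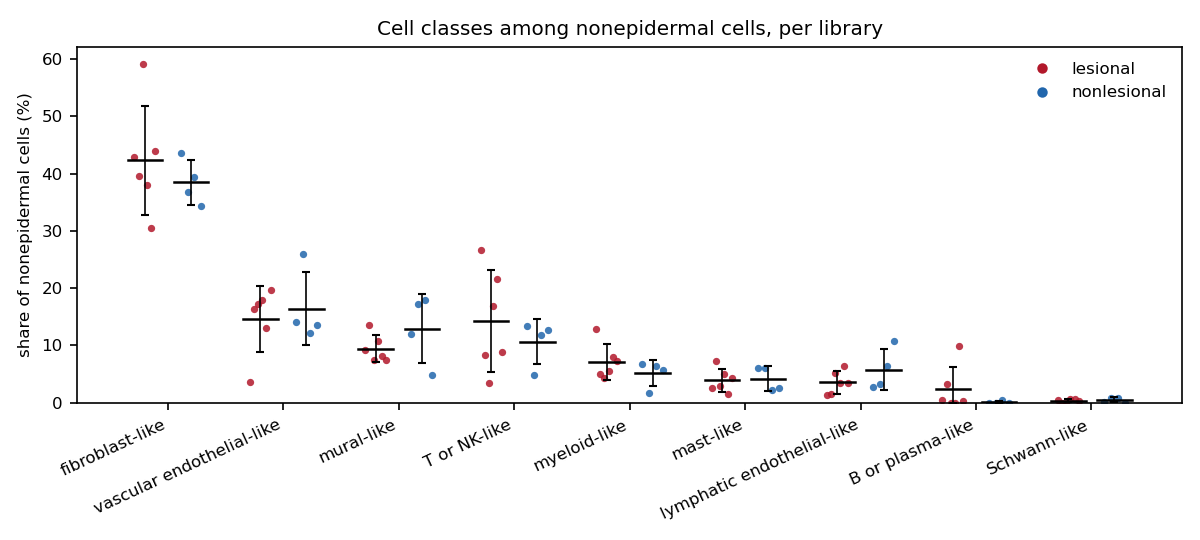
Share of 9 cell classes among nonepidermal cells in percent, with 1 point per library (6 lesional, 4 nonlesional), a horizontal line at the mean and bars of 1 SD that stop at 0. The groups overlap in each class, with fibroblast-like means of 42.4% and 38.5%.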

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

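A library was set apart when it lay farther from the rest of its group than Dixon's test allows at 95%. The test was run on CPM and on log2 values, and CPM was kept because the text prints CPM. Of 436 sets of a gene in a group of libraries 73 were set apart on CPM (62 of them by a high value) and 56 on the log2 scale, and of 28 sets of shares or library measures 4 were. Chance flags about 1 in 20 groups if values are normally distributed and independent. The CPM flags make up 16.7% of the gene sets. Most of them are high values, and genes were often flagged together in the same library, so that rate need not hold here. Whether chance alone gives their number therefore cannot be told, and neither can it for a single value.

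Lesional replicate 1 stood apart in keratinocyte-like cells, of which it has 82, with COL1A1 at 1760 CPM, COL3A1 at 668, TNC at 148, FLG at 5920, LOR at 5600, OASL at 27.2, HK2 at 25.5 and P4HA1 at 15.4. In the same class lesional replicate 5 had S100A2 at 10100 CPM and lesional replicate 3 IL31RA at 1.8. Nonlesional replicate 2, with 21 such cells, had KRT1 at 16300, IL13RA1 at 23.2, P4HA1 at 0, and CAPN2, OSMR, IL31RA and POLR3G at 11.6 CPM each, which for single molecules is set by its depth. Nonlesional replicate 5 was high in activation genes, with KRT16 at 1320, S100A9 at 1250, KRT6A at 834 and S100A8 at 705 CPM.

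The same nonlesional replicate 5 was high in these genes in other classes. It had KRT16 at 38.8 and SPRR1B at 8.32 CPM in T or NK-like cells, KRT6A and SPRR1B at 2.65 each and KRT6C at 0.443 in fibroblast-like cells, KRT16 at 11.4 in myeloid-like cells, and KRT6A and S100A9 at 6.84 each and KRT6B at 3.42 in vascular endothelial-like cells, where PPL stood at 20.5. Some of these values are few molecules. Over all nonlesional libraries KRT6C had 1 count in fibroblast-like, KRT16 2 in myeloid-like and KRT6B 2 in vascular endothelial-like cells.

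In fibroblast-like cells lesional replicate 1 had TNC at 2190 and SPHK1 at 171 CPM and lesional replicate 5 had WNT5A at 251. Nonlesional replicate 6 had COL11A1 at 98.2, FABP5 at 62.3, P4HA3 and UBE2C at 9.44 each and TOP2A at 3.77, and nonlesional replicate 1, with 31 cells, had SLC25A21-AS1 at 33.8 and CENPF and TGFB1 at 0. In T or NK-like cells JUNB stood at 739 in lesional replicate 1, OSM at 36.5 in lesional replicate 3, SLC38A2 at 182 in lesional replicate 4, S100A2 at 568 in lesional replicate 6, IL4R at 22.5 in nonlesional replicate 3 and EGR2 at 115 in nonlesional replicate 4.

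Lesional replicate 2 was high in collagen in myeloid-like cells, with COL1A1 at 7260, COL1A2 at 3850, COL3A1 at 3700 and SPARC at 1140 CPM, and in mural-like cells with COL1A1 at 15000. Other myeloid values set apart were IFITM3 at 811 in lesional replicate 1, GBP1 at 5.14 in lesional replicate 3, COL1A1 at 21.9, CCL20 at 35.8 and CXCL1 at 69.6 in nonlesional replicate 3, DMKN at 3590 and SBSN at 451 in nonlesional replicate 4 and IL13RA1 at 105 in nonlesional replicate 6. In mural-like cells OSMR stood at 177 and TPX2 at 59.9 in lesional replicate 1, ISG15 at 818 in lesional replicate 3 and GFRA1 at 15.1 in lesional replicate 6. In vascular endothelial-like cells lesional replicate 1 had COL4A1 at 2250, COL4A2 at 1900 and IL4R at 64.9, lesional replicate 2 BAG3 at 98.2, lesional replicate 4 OTULINL at 12.1, lesional replicate 6 INSR at 46.3, and nonlesional replicate 6 SPARC at 298 and TGFB1 at 60.9. Among shares, B or plasma-like cells made up 9.94% in lesional replicate 5 and 0.425% in nonlesional replicate 5, vascular endothelial-like cells 25.9% in nonlesional replicate 4 and unnamed clusters 16% in nonlesional replicate 6.

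Contrasts also differed between cell classes, and the 3 class pairs here were picked because their lists were called in opposite directions, so the differences restate those calls. The TGF-beta response list rose in fibroblast-like and fell in T or NK-like cells (adjusted p = 0.2058 and 0.2559 with an estimated correlation), a difference of 1.056 (exact permutation p = 0.00952), and the difference between vascular endothelial- and T or NK-like cells was 0.936 (exact permutation p = 0.019). The immediate early and heat shock list differed by 1.026 between vascular endothelial- and T or NK-like cells (exact permutation p = 0.00952). Between basal and suprabasal keratinocyte-like cells 507 of 13489 genes had different contrasts.

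Genes of another cell type were higher in several lesional classes, and of the tests below those against DCN and LUM and that of activation genes in myeloid-like cells were chosen after the first results were seen. If free keratinocyte RNA were the cause, activation genes would keep the ratio to keratinocyte markers found in keratinocyte-like cells of the same library. Keratin, SPRR and SERPINB members lay at a log2 ratio of −1.42 from it and other activation members at 0.44, so free RNA may explain the second set, while the first cannot be told. In myeloid-like cells the other members lay at 1.96, which does not tell free RNA from transcription there, and S100A8 is also a gene of myeloid cells. Collagens lay at −2.9 from fibroblast markers in keratinocyte- and myeloid-like cells together, which cannot be told. Against DCN and LUM alone the joint value of −1.28 covers 2 classes that differ. It was 0.08 in myeloid-like cells, where fibroblast RNA may explain the collagens, and −2.68 in keratinocyte-like cells, where it cannot be told. The myeloid value rests largely on few molecules, with 6, 8, 19 and 1 counts of DCN and LUM in lesional replicates 3 to 6. Lesional replicates 1 and 2, with 487 and 728 counts, lay at 0.108 and 0.178, and the others ranged from −2.378 to 0.196. Keratinocyte-like cells of lesional replicate 1, the library high in COL1A1, lay at 0.552, so fibroblast RNA may explain the collagens there. The other lesional libraries lay at −3.809 to −2.145 in this class. With all 4 fibroblast markers the median was −3.03 in myeloid-like cells, so the reading in myeloid-like cells depends on the markers.

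The immediate early and heat shock list was lower in lesional T or NK-like cells and in epidermal classes, basal and suprabasal keratinocyte-like cells among them. It was higher in lesional vascular endothelial-like cells. All 3 tests were chosen after this was seen, and no call of the list held with an estimated correlation. In keratinocyte-like cells as 1 class it was not called (median log2 −0.88, difference of list means 0.04, exact permutation p = 1). A single handling effect on all cells of a library would give no difference between these classes, and the difference was 1.026 (exact permutation p = 0.00952). It stays open, since the 2 classes were picked for their opposite directions and the rise in vascular endothelial-like cells alone has an exact permutation p of 0.195. A handling effect on the epidermal suspension alone could explain the dermal against epidermal difference of 1.24 (exact permutation p = 0.00476). The fall in T or NK-like cells (exact permutation p = 0.0143) does not decide it, since the layer these cells came from is unknown. A biological difference of the lesion would part the groups in the same way.

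The matrix list was higher in lesional fibroblast-like cells, and the test within the cluster with the larger median was chosen after the result was seen. For depth, 6 lesional and 4 nonlesional libraries were thinned to 518079 UMIs, and nonlesional replicate 1, with 39005 UMIs, was left out. The median log2 fold change was 1.01 after thinning (43 members tested) and 1.08 in the same libraries before (48). Deeper lesional sums are therefore excluded in these libraries. A different mix of clusters alone cannot be told in cluster 5, where the median was 0.47 (exact permutation p = 0.0857, 4 libraries in each group). In cluster 8 it was 0.85 (exact permutation p = 0.00216), so a mix of clusters alone is excluded there. A different mix of cells within cluster 8 and free RNA from other fibroblast-like cells were not tested. They cannot be told apart from a change of the cells in the nodule, and the sources of cells were not tested.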

How the results depend on the processing

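Counts of calls depended on the libraries, since a comparison rests on 3 to 5 nonlesional libraries, and the cause was not tested unless fewer libraries or genes show it. Counts in fibroblast-, keratinocyte-, T or NK-, myeloid-, vascular endothelial- and mural-like cells were 661, 1987, 16, 0, 95 and 5. With the block they were 1253, 3876, 26, 2, 598 and 401, and leaving out 1 library gave 109 to 908, 591 to 2833, 0 to 17, 0 to 5, 5 to 285 and 1 to 77. In the last 4 of these classes DESeq2 called 46, 34, 313 and 161 and no low-count filter 149, 1, 213 and 95. Patients with both libraries gave 1 (T or NK), 236 (vascular) and 90 (mural), at least 50 cells 3, 31 and 23, the strict cell filter 6 (T or NK), and at least 10 cells 39 and marker-score classes 37 (mural). Thinning to equal UMIs, without nonlesional replicate 1, gave 201 (fibroblast).

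In basal keratinocyte-, suprabasal keratinocyte-, lymphatic endothelial-, mast-, melanocyte-, Langerhans- and adnexal epithelium-like cells the counts were 1640, 2898, 86, 0, 74, 14 and 0. Leaving out 1 library gave 484 to 2132, 1186 to 3505, 8 to 90, 0 to 0, 1 to 129, 0 to 72 and 0 to 7. The block gave 2848 in basal keratinocyte-like cells. In the last 5 classes the block gave 226, 2, 155, 37 and 31, DESeq2 149, 31, 148, 43 and 25, and no low-count filter 375, 60, 529, 282 and 11. Marker-score classes gave 43 (lymphatic), at least 10 cells 347 and doublets kept 117 (melanocyte), patients with both libraries 2 (Langerhans) and 7 (adnexal) and the strict filter 0 and 7. The 507 genes whose contrasts differed between basal and suprabasal keratinocyte-like cells became 957 without the low-count filter and 133 to 479 without 1 library.

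Of 177 list tests 62 passed, 0 with an estimated correlation, 14 with fry and 0 by exact permutation after adjustment. Of the camera calls 39 had an unadjusted permutation p under 0.05. The arrangements set a floor for that p, such as 0.00476 with 210, which limits what can pass after adjustment over 177 pairs. The neurotrophin list in fibroblast-like cells turned from a median of −0.36 to a difference of list means of 0.065. In the main classes the block ended or added no list call other than those printed, and it changed the call of no gene whose test is printed for a class other than those given with it.

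No share passed under any denominator. With all cells as denominator the differences in points were 2.02 (mural), 3.02 (vascular), 0.98 (lymphatic), 0.78 (mast) and 0.11 (Schwann), which mixes in the epidermal share, and 14.3 (fibroblast), 7.15 (T or NK), 3.27 (myeloid) and 1.38 (B or plasma), with a permutation adjusted p of 0.3762 for each class. Vascular cells gave 0.54 with the block, mast cells 1.12 with all libraries and 1.41 under the strict filter, and Schwann cells 0.02 with all libraries and 0.01 with doublets kept. Without 1 library the ranges were 0.49 to 6.23 (fibroblast), −6.27 to −1.91 (mural), −3.2 to 1.38 (vascular), −3.25 to −0.6 (lymphatic), 1.15 to 5.81 (T or NK), 0.67 to 2.66 (B or plasma), 0.89 to 2.6 (myeloid), −0.95 to 0.36 (mast) and −0.28 to 0 (Schwann).

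Over all alternatives 4514 gene or contrast differences kept direction and side of the threshold, 226 lost and 186 gained the call and 40 moved. Of list results 614 kept it, 131 lost it and 1 reversed. Among the main classes the test recovered the fewest simulated 4-fold changes in myeloid-like cells (53%), and whether depth is the cause was not tested.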

Other observations

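Among the secondary classes, basal and suprabasal keratinocyte-like cells each carried the interferon program. In basal cells 15 of 21 interferon genes rose and 0 fell (median log2 2.11, camera adjusted p = 4.386e-16, adjusted p = 0.2058 with an estimated correlation), with IFITM3 at log2 2.03 (SE 0.21, n = 5 lesional and 4 nonlesional). In suprabasal cells 19 of 21 rose (median log2 3.29, camera adjusted p = 7.587e-14, adjusted p = 0.2283 with an estimated correlation), with IFITM3 at log2 3.22 (SE 0.40, n = 6 and 4). The basal keratins KRT5 (log2 3.15, SE 0.46) and KRT14 (log2 4.34, SE 0.86) and the integrin ITGA6 (log2 1.47, SE 0.35) rose in suprabasal cells, where 8 of 17 basement membrane genes were higher (adjusted p = 0.539 with an estimated correlation for the list). The class holds different clusters in each group: clusters 10 and 15, whose next best class is basal keratinocyte, came to 95.9% and 96% from lesional libraries, and clusters 22 and 23 to 9.64% and 18.3%. Immediate early genes fell in both, 14 of 22 in basal cells with JUN at log2 −1.46 (SE 0.26) and 12 of 22 in suprabasal cells with JUNB at log2 −1.20 (SE 0.23) (adjusted p = 0.2058 and 0.3197 with an estimated correlation for the lists). The lesional against nonlesional contrast of SPARC was log2 0.27 in basal and 3.14 in suprabasal cells, a fitted difference of 2.76. That of CYP26B1, which degrades retinoic acid, was log2 2.1 in basal and −1.73 in suprabasal cells, a fitted difference of −3.74. Counts were 1640 and 2898 genes.

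In lymphatic endothelial-like cells 86 genes passed, of which 29 are ribosomal protein genes, all lower (median log2 −0.61 over 82 tested), and whether RNA quality or depth is the cause was not tested. Matrix genes were among the others. SPARC rose by log2 3.16 (SE 0.38, n = 5 and 4), ELN, elastin, by 1.66 (SE 0.31), COL4A2 by 1.17 (SE 0.24) and COL4A1 by 1.05 (SE 0.23). The matrix list (5 of 14 higher) and the endothelial list (3 of 8 higher) rose with adjusted p = 0.1025 each with an estimated correlation. The 3 higher genes of the endothelial list are SPARC, COL4A1 and COL4A2, which the matrix list also holds. In melanocyte-like cells IFI6 rose by log2 2.06 (SE 0.38, n = 3 and 4) and ISG15 by 2.48 (SE 0.46), while BCL6 fell by log2 1.80 (SE 0.33), JUN by 1.33 (SE 0.24) and STMN1 by 1.31 (SE 0.22), among 74 genes. Of 11 lists tested in this class 6 were called, 1 higher and 5 lower, and none with an estimated correlation. In Langerhans-like cells the interferon gene MX1 rose by log2 3.03 (SE 0.44, n = 4 and 4) among 14 genes, along with the macrophage markers CD14 (44 counts against 7), C1QC (134 against 9) and CYBB (log2 2.18, SE 0.36, edgeR adjusted p = 0.0293, and 0.0651 with the block). Adnexal epithelium-like cells had 0 genes called (517 at an unadjusted p under 0.05, 25 by DESeq2) and mast-like cells 0 (193 and 31). With the block the hypoxia list of suprabasal cells lost its call (camera adjusted p = 0.0355 without and 0.2009 with it). It added the JAK-STAT (lower, 0.03009) and endothelial (0.001394) lists there, TGF-beta in lymphatic (lower, camera adjusted p = 0.0146), cornified envelope in Langerhans (lower, 7.803e-07) and activation (6.39e-05) and basement membrane (0.002341) in adnexal epithelium-like cells.

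All split counts below except that of the 507 genes were added after the results were seen, and they say only whether chance can be excluded. With the libraries split into groups of the same sizes, 1 of 100 splits, the real one, reached the 1987 calls of keratinocyte-like cells (highest other 947) and the 95 of vascular endothelial-like cells (highest other 40). In fibroblast-like cells 2 of 100 reached 661, the other being the real split with lesional replicate 4 moved (710). Only 6 of the other splits drawn part all pairs. They called at most 14, but are too few to exclude chance by themselves. In T or NK-like cells 2 of 100 reached 16 (highest other 36). In mural-like cells a split with lesional replicates 1, 3 and 5 apart called 73 genes against the real 5, which points to a structure among the lesional libraries. The real split was the only one as large in basal (highest other 2 of 100 splits), suprabasal (1041), lymphatic endothelial (3), melanocyte (8 of 35 splits) and Langerhans-like cells (6). The same held for the 507 genes whose contrasts differed between the layers (133). Counts of lists called do not exclude chance: 57, 90, 19, 21 and 49 of 100 splits reached the real 6, 5, 5, 6 and 6 lists in fibroblast-, keratinocyte-, T or NK-, myeloid- and vascular endothelial-like cells, and 59 of 84 the 4 in mural-like cells.

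The interferon list was higher in several lesional classes, and a level shared by all cells of a lesion was tested as a hypothesis. Over the 6 lesional libraries the list mean of keratinocyte-like cells correlated with that of T or NK-like cells at r = 0.26 and with that of mural-like cells at r = −0.09 (permutation test, smallest adjusted p = 0.864). Without the 2 farthest libraries these were −0.2 and 0.81, so 6 libraries cannot tell.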
